A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

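Binding of 5 proteins to fission yeast (Schizosaccharomyces pombe) DNA was measured by chromatin immunoprecipitation on tiling microarrays (ChIP-chip). The 9 two-colour arrays covered GFP-tagged Bqt3, Mcm6, Sap1 and GFP-tagged Psc3 in wild type and in the mutant sap1-1, and Taz1-GFP in wild type only. Each of the 9 combinations of protein and genotype had 1 array, so the arrays had no replicates. Per the labels, cultures grew in rich medium at 26 °C and were shifted to 33 °C for 6 h, and hydroxyurea served to arrest cells in S phase, without a statement of which cultures received it. Per the labels, cells were fixed with 3% paraformaldehyde and then with DMA for 45 min, chromatin was sheared to 500 to 1000 bp, and precipitates were taken with antibodies to GFP, Sap1 or Mcm6. Per the labels, the DNA was amplified by random-primed PCR, the ChIP DNA was labelled with Cy5 and the whole-cell extract DNA with Cy3. The labels give no further account of how the deposited values were made.

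Per the file headers, the spot files came from Agilent Feature Extraction, version 11.5.1.1 for both Bqt3 arrays and the Taz1 array, 10.7.3.1 for both Mcm6 arrays, 9.5.1.1 for Sap1 in wild type, and 11.0.1.1 for Sap1 in sap1-1 and both Psc3 arrays. Per the file headers, the processed signal of each channel is an intensity after background subtraction and dye normalization within the array. Per the file headers, a log10 ratio of Cy5 over Cy3 is also given, and in all 9 files it equalled the log10 ratio of the processed signals, with a largest difference of 1e-06. A deposited table of 41251 probes per array held log2 ratios for the Sap1, Taz1 and Psc3 arrays, uncentred, with medians of −0.06 and 0.01 for Sap1 (wild type, then sap1-1), −0.05 for Taz1, and 0.17 and 0.17 for Psc3. For Bqt3 the deposited values were log2 ratios averaged over 5 neighbouring probes, with medians of 0.00 in wild type and −0.03 in sap1-1. For Mcm6 the deposited values were a score on a linear scale, with medians of 0.938 and 0.961, whose formula was not recovered. These units were read from the values, since neither the labels nor the headers state them for the table.

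Analyses used the processed signals of the spot files. Spots that Feature Extraction marked as non-uniform or as population outliers (3 to 760 per array) were removed, and saturated spots were kept. The log2 ratio of ChIP over whole-cell extract was centred on the median of the probes placed on the nuclear chromosomes, with no further normalization. The 41551 probes of 60 bases were aligned to the reference assembly ASM294v3 with bwa 0.7.19 (minimum score 50, seed length 15). Of these, 40396 had 1 exact match, 1053 had several and 102 had none. A probe with several matches was placed at the match nearest to the position in its name, if within 10 kb, which put 41309 probes on chromosomes I to III with a median spacing of 300 bp. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9, with R 4.3.3 and limma 3.58.1 for background correction and loess.

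An enriched region was a run of at least 3 consecutive probes, with gaps of at most 1500 bp, whose running mean over 3 probes was at least 1 on the log2 scale (2-fold). For comparisons of genotypes, regions were found on the average of both arrays of a protein. Subtelomeres were the 100 kb next to each end of chromosomes I and II. A centromere was the longest interval of a chromosome without a protein-coding gene and more than 100 kb from an end. Genes were given the mean over probes measured on all 9 arrays that lay within the gene or 500 bp on either side, and 5389 of the 5435 annotated genes had at least 3 such probes. Intergenic regions on chromosome arms were classed as convergent, divergent or tandem by the strands of the neighbouring genes.

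With 1 array per protein and genotype, no test between genotypes of a protein was possible, and differences (sap1-1 minus wild type) are given with their spread over regions or probes. The number of arrays limits the precision, and intervals describe the variation along the chromosomes of these arrays and not that between cultures. Medians over regions carry 95% bootstrap intervals (2000 draws), and means over classes carry standard errors (SE) over blocks of 20 kb. The position of a mean among 10000 circular shifts of the same regions along the tiled genome, or of a gene list among 10000 random lists matched on mean level in 10 bins, is given as a percentile that describes these arrays. A gene or list is said to have risen or fallen when all probes of the gene moved in that direction or when the list's median difference lay outside the central 95% of the matched lists, and a class when its mean difference lay outside the central 95% of the shifts. Neighbouring probes of a gene can share sheared fragments and are not independent. Counts of such genes describe these arrays, and without replicates no share expected between like arrays was available. Enriched regions are said to have risen or fallen when the 95% interval of their median difference excluded 0. The whole-cell extract channel holds genomic DNA of 5 wild-type and 4 sap1-1 cultures and was compared between genotypes by an exact two-sided permutation test, after each probe's mean over all arrays was removed. Slides and scanners were numbered from the file headers and served as batches.

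The comparisons, thresholds, gene lists and 20 of the processing alternatives were fixed before the data were examined. The rule for named genes took the genes nearest to the 10 most enriched regions of each protein, and the 5 largest rises and 5 largest falls among genes all of whose probes moved in that direction, at most 1 per 5 kb. It also took up to 4 members of each gene list by the size of the change. Exceptions, chosen after their values were seen, were genes at DNA absent from a strain, and nmt1 and hus5. The 8 fixed lists were MBF target genes (12), heat and stress genes (10), histone genes (11), meiotic genes of facultative heterochromatin (14), glycolytic genes (9), translation factor genes (7), plasma membrane transporters (8) and subtelomeric helicases (2). The annotation supplied tRNA genes, 5S rRNA genes, ribosomal protein genes, long terminal repeats and Tf2 elements.

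Each result was recomputed with normexp background correction (offset 50) on the median spot signals, since 8 of the 9 files lack mean signals, and with the deposited table where it holds log2 ratios. Further alternatives were centring on the mode, scaling both arrays of a pair to one robust SD, quantile normalization within the pair, loess within each array (span 0.3, 4 iterations), probes well above background and not saturated, and probes with 1 match. Regions were also called at 1.5-fold, at 3-fold, at 3 robust SDs and with a 5-probe window, and on either array alone, and subtelomeres were also taken as 50 kb and as 20 kb. The whole-cell extract comparison was repeated within slides and scanners, after quantile normalization and without each array in turn. A further 6 alternatives were added after seeing the data: intergenic regions bounded by coding sequences, the ChIP channel alone, no regions with a saturated probe, a shorter motif, no probes whose whole-cell extract signal lay 8-fold or more below the median of the arrays, and the whole-cell extract arrays paired by protein.

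The steps were tested on simulated data. Of 200 planted regions 199 were found with 0 false regions, a planted difference of −1 came back as a median of −0.95, and a subtelomeric difference of 1.5 came back as 1.51. Of 200 raised genes 197 had all probes higher, and 2 of 200 unchanged lists lay outside the central 95% of matched lists. The simulated arrays had noise of equal spread, and the lists were drawn at random. These rates need not hold for arrays of unequal spread or for lists of clustered genes. In 200 simulations without a genotype difference, 5 gave an exact permutation p under 0.05 for the whole-cell extract.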

Results

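ChIP-chip arrays recorded where 5 chromosomal proteins sat in fission yeast: Sap1, an essential DNA-binding protein first known for its part in mating-type switching; Mcm6, a subunit of the replicative MCM helicase; Bqt3, an inner nuclear membrane protein; Psc3, a subunit of cohesin; and Taz1, the telomere repeat-binding protein of shelterin. Sap1, Mcm6, Bqt3 and Psc3 were each profiled on 1 wild-type and 1 sap1-1 array, and Taz1 on 1 wild-type array, which makes 9 groups of 1 array without replicates. The series title frames the work around shelterin, the arrangement of the genome and replication stress. Median spot signals ranged from 15976.5 to 26602.2 in the whole-cell extract channel and from 12307.5 to 30241.0 in the ChIP channel. From 99.9% to all of the probes in each channel of each array were well above background, and the noise between neighbouring probes was 0.10 to 0.14 on the log2 scale. All values below are centred log2 ratios of ChIP over whole-cell extract, differences are sap1-1 minus wild type, and positions are on assembly ASM294v3.

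Sap1 in wild type against sap1-1 shows where the protein encoded by the mutated gene remained on chromatin. Sap1 was enriched at least 2-fold at 216 regions in wild type, 197 of them on chromosome arms, and at 2 regions in sap1-1, with 0 regions shared. At the 46 regions enriched on the average of both arrays the median fell from 2.29 to 0.20, a difference of −2.14 (95% interval −2.27 to −1.95), and all 46 were lower in sap1-1. The sap1-1 array had a narrower spread (robust SD 0.19 against 0.31). An average of at least 1 therefore mostly needed high wild-type values, so this choice of regions favours a fall. At the 216 wild-type regions the median fell from 1.52 to 0.10, and all 216 were lower, which the choice of regions on the wild-type array favours; the 2 regions chosen on the sap1-1 array were both higher there. Runs of probes depleted at least 2-fold numbered 2 in wild type and 1 in sap1-1.

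The strongest averaged region lay within the retrotransposon Tf2-2 (chromosome I, 1563618 to 1564590), at 3.44 in wild type and 0.08 in sap1-1. Of its 3 probes 1 was saturated in wild type and 2 in sap1-1, so its levels and rank are inexact. The region beside mat1-Mc (chromosome II, 2115500 to 2116632), next to the site of mating-type switching, stood at 1.81 in wild type and 0.89 in sap1-1, the latter inexact because 6 of its 8 probes were saturated in sap1-1 and 0 in wild type. Upstream of wtf15, of a family of spore-killer genes, the signal was 2.86 in wild type and 0.16 in sap1-1 (chromosome III, 1632094 to 1632815). Beside vps5, a retromer gene, it was 2.62 and 0.29, within kcs1, an inositol phosphate kinase gene, 2.14 and 0.42, and upstream of coa6, a cytochrome c oxidase assembly gene, 2.75 and 0.06. The other 4 of the 10 strongest regions lay at SPBPB10D8.07C (2.59 and 0.53), SPBPB10D8.06C (2.21 and 0.52), SPBC8E4.03 (2.17 and 0.32) and SPAC27E2.01 (2.47 and 0.22). The 2 regions found in sap1-1 lay at nmt1, the thiamine-repressed gene (chromosome III, 1839738 to 1840307; −0.22 in wild type and 1.79 in sap1-1), and at hus5, which encodes the SUMO-conjugating enzyme (chromosome I, 1095469 to 1096193; −0.05 and 1.34).

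Among the gene groups, retrotransposon sequences had the most negative Sap1 differences. The median over 9 Tf2 elements fell from 2.32 to −0.16 (difference −2.54), with all probes lower in all 9, among them Tf2-2 (−2.82), Tf2-9 (−2.81), Tf2-3 (−2.72) and Tf2-1 (−2.57). On the sap1-1 array most of their probes were saturated in the ChIP channel (2 of 3, 5 of 5, 4 of 5 and 4 of 4) and in the whole-cell extract channel (2, 5, 3 and 4). A ratio of saturated channels does not measure binding. The sap1-1 levels at such probes, and with them the size, direction and order of the changes at these elements, are not known. Over 212 long terminal repeats (LTRs) the median fell from 1.32 to 0.13 (difference −1.22, quartiles −1.57 to −0.71), with all probes lower in 184 and higher in 11. Both medians lay below those of all 10000 matched random lists. Neighbouring members can share probes, as the LTRs at 3995538 and 3996024 of chromosome I do. Members are therefore not independent, and the comparison with random lists can overstate how far these groups stand apart. Quantile normalization brought the median differences of Tf2 elements and LTRs to −1.63 and −0.66. The 152 tRNA genes had medians of 0.31 and 0.25 (difference −0.10, less negative than all 10000 lists matched on level), a difference that changed sign to 0.03 with both arrays scaled to one robust SD and to 0.15 with quantile normalization, and SPBTRNATRP.02 had −1.21. The 35 5S rRNA genes had medians of 0.43 and 0.48 (difference −0.02, above all matched lists), which became 0.20 and 0.63 under those scalings, and SPRRNA.37 had −1.20. Ribosomal protein genes (141) had medians of 0.37 and 0.15 (difference −0.20, percentile 99.46, a smaller fall than in most matched lists), with all probes lower in 47, rpl4102 (−0.92) among them, and higher in 3; it was −0.10 with scaling to one robust SD, −0.03 with quantile normalization and −0.33 with normexp. Translation factor genes (7) had medians of 0.69 and 0.14, a difference of −0.48 at percentile 42.58 that was −0.01 with quantile normalization, with all probes lower in 5, among them the elongation factor genes tef101 (−0.74) and eft201 (−0.63). The median differences of the other lists lay within the central 95% of matched lists: −0.19 for glycolytic genes (tpi1, triosephosphate isomerase, −0.58), −0.05 for heat and stress genes (the Hsp70 gene ssa2, −0.64), −0.14 for histone genes (hta1, −0.28), 0.04 for MBF targets, 0.09 for meiotic genes (mcp7, −0.52) and −0.07 for plasma membrane transporters (the siderophore transporter gene str3, 1.02). The signs for MBF targets and transporters changed under centring on the mode and quantile normalization, respectively. Of the 2 subtelomeric helicase genes, tlh1 was measured and stood at 1.14 in wild type and −0.05 in sap1-1.

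Sap1 signal in subtelomeres went the other way, from −0.07 in wild type to 0.32 in sap1-1, a difference of 0.40 (SE 0.11, 1132 probes, percentile 99.6 among shifts). Within the class the difference was 0.61 (SE 0.08) from 50 to 100 kb. Over the outer 50 kb it was 0.10 (SE 0.17, percentile 93.73), within the central 95% of shifts, an average of opposite changes. The first 10 kb fell from 0.92 in wild type to 0.12 in sap1-1. The bin from 30 to 40 kb rose from −0.06 to 0.24, and that from 40 to 50 kb from −0.27 to 0.33. From 90 to 100 kb the levels were 0.20 and 0.27. The 4 subtelomeric regions among the 46 averaged ones all fell (median −1.82). The rise extended beyond the class, with 0.09 in wild type and 0.32 in sap1-1 from 100 to 110 kb. Quantile normalization gave 0.73 over the whole class and normexp 0.64, and unsaturated probes 0.51. In the ChIP channel 130 of 1149 probes were saturated in sap1-1 and 0 in wild type. Over all placed probes the Sap1 sap1-1 array correlated at 0.30 with Mcm6 sap1-1, 0.24 with wild-type Psc3 and 0.21 with wild-type Sap1. On arms these correlations were 0.19, 0.22 and 0.26. The subtelomeric rise therefore need not be Sap1 binding. Of the 5 largest rises of single genes 4 lay in subtelomeres and pfl7 just beyond, at SPAPJ695.02 (1.26), SPAC869.04 (1.25), hry1 (1.15), pfl7, a cell-surface glycoprotein gene (1.12), and SPBPB8B6.02C (1.1). All probes rose in 499 genes and fell in 814. The 5 largest falls by value were Tf2-2, Tf2-9, Tf2-3, Tf2-1 and Tf2-5 (−2.54, with 5 of 7 probes saturated in each channel in sap1-1). Saturation in both channels leaves these falls unsettled. Centromeres had a difference of −0.34 (SE 0.05, percentile 0.38), but on the sap1-1 array at least 101 of their 361 probes were saturated in each channel, against 0 in wild type. Unsaturated probes gave −0.11 (95% interval −0.30 to 0.08), loess −0.06 and normexp −0.04, so this fall is uncertain. The pair of Sap1 arrays differed in slide, scanner and software version, and of the 46 regions 29 held a saturated probe, without which the median difference over the other 17 was −1.76. The median was −1.483 with scaling to one robust SD. With quantile normalization it was −0.46 (95% interval −0.58 to 1.15) over the 15 regions enriched on that scale, so the fall is not called there; at the original 46 regions the same normalization gave −1.11 (95% interval −1.30 to −1.02), with 45 lower. The labels give a Sap1 antibody for both arrays, but the deposit of the wild-type array also carries a name that points to a tagged strain, so it is not settled that both precipitations were of one kind.

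**Figure D1:**
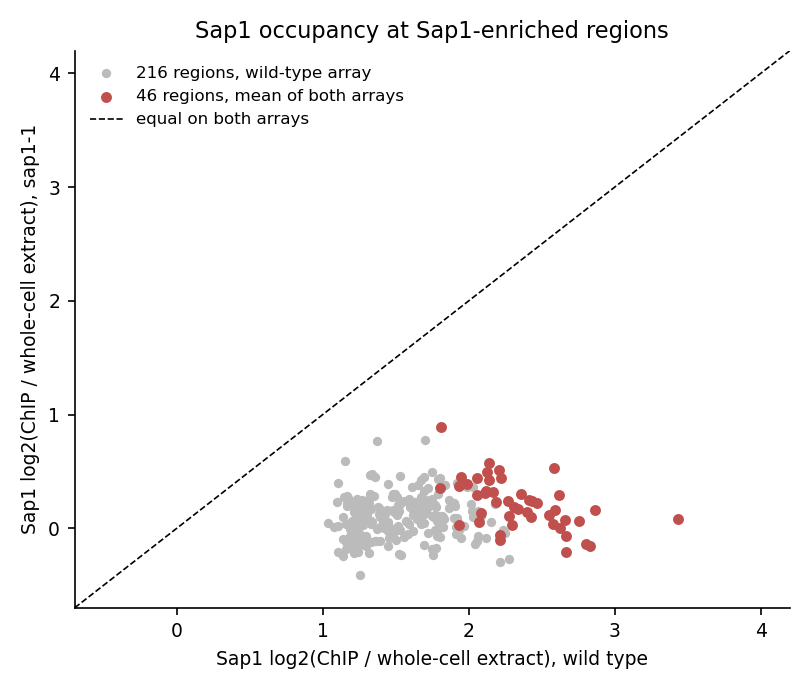
Sap1 log2 ratio in wild type (x axis) against sap1-1 (y axis) at the 216 regions enriched in wild type (grey points) and the 46 regions enriched on the average of both arrays (red points), with a dashed line of equality. All 46 averaged regions lie below the line, with medians of 2.29 in wild type and 0.20 in sap1-1.

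Mcm6 in wild type against sap1-1 shows whether the helicase that is loaded at replication origins sat at the same places and levels. Mcm6 was enriched at 401 regions in wild type and 141 in sap1-1, and 128 of the 141 overlapped a wild-type region by at least 1 bp. Depleted runs numbered 20 and 8. At the 234 averaged regions the median was 1.73 in wild type and 1.17 in sap1-1, with 196 lower, a difference of −0.56 (95% interval −0.63 to −0.46) that changed sign to 0.29 when both arrays were scaled to one robust SD. The 204 arm regions had a median difference of −0.63, and the 27 subtelomeric regions one of −0.25. At regions defined on the wild-type array alone the median difference was −0.81, and at those defined on the sap1-1 array alone −0.25. Across all placed probes the log2 ratios of both arrays had a Pearson correlation of 0.78, over probes that are not independent replicates.

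The most enriched regions lay at the ends of chromosomes. The regions nearest to SPRRNA.47 (chromosome III, 3814 to 5340) and SPRRNA.48 (13308 to 16126) lay within the rDNA. They stood at 2.73 and 2.83 in wild type and at 2.86 and 2.91 in sap1-1. Next came long stretches of subtelomeric DNA nearest to SPBPB2B2.18 (chromosome II, 4488128 to 4508918; 2.53 in wild type and 2.23 in sap1-1), ftm3 (chromosome I, 5517977 to 5570367; 2.34 and 1.76), ftm6 (chromosome II, 610 to 18729; 2.60 and 2.14) and SPAC977.18 (chromosome I, 112 to 50866; 2.54 and 2.07). The rest of the first 10 lay near SPAC750.07C (2.88 and 2.02), SPBPB2B2.06C (2.14 and 2.07), SPBC1348.08C (2.21 and 2.16) and the alpha-galactosidase gene mel1 (2.02 and 1.77).

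Subtelomeres as a class had a mean Mcm6 level of 1.88 in wild type and 1.65 in sap1-1, a difference of −0.22 (SE 0.07, 1119 probes, percentile 1.62 among shifts) that became positive with scaling to one robust SD (0.79), quantile normalization (0.16), normexp background correction (0.15) or the ChIP channel alone (0.08), the last 2 with intervals that include 0. The outer 50 kb went from 2.48 to 1.98 and the inner 50 kb from 1.44 to 1.41. Single genes with the largest falls were tam11 (−1.35), the ribosomal protein gene rpl3703 (−1.33), SPAC186.04C (−1.30), the mitochondrial import gene tim13 (−1.30) and mug15 (−1.25), all of which stayed negative under the scalings tried. The largest rises were at SPBC713.14C (1.13), dbl7 (0.86), the alanine racemase gene alr2 (0.86), SPCC622.07 (0.82) and ecl3 (0.71). All probes fell in 853 genes and rose in 585.

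Of the gene groups, heat and stress genes fell in Mcm6 from a median of 0.05 to −0.13 (difference −0.18, 10 genes, below all but 1.5% of matched lists; −0.31 with normexp), with all probes lower in 4; hsp16, a small heat-shock protein gene, went from 1.18 to 0.37, and wos2 (−0.47), hsp104 (−0.45) and hsp9 (−0.44) were next. Ribosomal protein genes fell by 0.14 at the median (below all matched lists), with all probes lower in 40 and higher in 7 (−0.08 with loess, −0.22 with normexp and with centring on the mode), and LTRs fell by 0.12 (percentile 0.01; −0.21 with centring on the mode), with 78 lower and 21 higher. Glycolytic genes were low in both genotypes, at −0.45 and −0.50 (difference −0.04, percentile 0.07), which became −0.33 with scaling to one robust SD, −0.19 with quantile normalization and −0.12 with centring on the mode. Tf2 elements rose from 0.83 to 1.02 (difference 0.18, percentile 99.99), with all probes higher in 1 of 9; the difference was 0.71 with scaling to one robust SD, 0.57 with quantile normalization, 0.10 with normexp and 0.08 with centring on the mode. The 5S rRNA genes had a median of 0.34 in both genotypes, with a median difference of −0.06 (above all matched lists) that was 0.08 with scaling to one robust SD, 0.10 with quantile normalization and 0.01 with normexp. The remaining lists lay within the central 95% of matched lists, with median differences of −0.11 for tRNA genes (−0.24 over the 110 on arms, percentile 0.12), −0.07 for MBF targets, −0.01 for histone genes (hta1, 0.40), −0.09 for meiotic genes (mcp7, −0.60), −0.12 for translation factor genes, which was positive under 3 of the scalings tried (0.02 to 0.11), and 0.10 for transporters (the copper transporter gene ctr4, 0.50). The helicase gene tlh1 went from 2.49 to 1.5, a difference that became 0.11 with scaling to one robust SD. The wild-type array had a wider spread than the sap1-1 array (robust SD 0.44 against 0.25), and scaling both arrays to one robust SD turned the differences over enriched regions and over subtelomeres positive.

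Bqt3 in wild type against sap1-1 asks which DNA lay near the nuclear membrane in each genotype. In wild type Bqt3 was enriched at 21 regions, of which 7 lay in subtelomeres, 6 at centromeres, 5 at the rDNA ends and 3 on arms; 3 of the 7 subtelomeric ones, at pan5, tgd1 and gal1, lay in DNA missing from that extract and do not measure binding. In sap1-1 it was enriched at 101 regions, 76 of them on arms and 18 in subtelomeres. Depleted runs numbered 0 and 23. Subtelomeres of chromosomes I and II rose from a mean of −0.00 to 1.90, a difference of 1.91 (SE 0.13, 1136 probes, percentile 99.84 among shifts). Of the 1149 subtelomeric probes 353 were saturated in the ChIP channel in sap1-1 and 74 in wild type, so the size is inexact, and unsaturated probes gave 2.07. Centromeres fell from 1.20 to 0.48, a difference of −0.72 (SE 0.05, 356 probes, percentile 0.04). Of their 361 probes 119 in wild type and 90 in sap1-1 were saturated in the ChIP channel, and 70 and 86 in the whole-cell extract, so this size is inexact too: it was −0.95 over the 239 unsaturated probes, −1.13 with scaling to one robust SD and −1.19 with normexp.

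The subtelomeric rise held at each end: 1.74 and 1.95 at the left and right ends of chromosome I, and 2.33 and 1.56 at those of chromosome II. The last includes 49 probes missing from the wild-type extract, without which it was 1.65 (SE 0.28, 164 probes). In wild type the 10 kb nearest the ends averaged 0.72 and the bin from 40 to 50 kb averaged −0.06, against 1.476 and 2.35 in sap1-1. The rise extended beyond the subtelomeres, with a difference of 0.80 (SE 0.15) from 100 to 200 kb. The 5 genes with the largest rises were SPBPB8B6.02C (at least 2.85), SPBPB10D8.03 (at least 2.80), alr2 (at least 2.75), SPBC1348.11 (at least 2.73) and SPBPB10D8.01 (at least 2.72), where saturated probes on the sap1-1 array make the values lower bounds. All probes rose in 1633 genes and fell in 1981.

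The 10 strongest averaged regions included 5 at the rDNA ends of chromosome III, among them SPRRNA.42 (26 to 8069), at 2.17 in wild type and 2.35 in sap1-1, SPRRNA.48 (2.07 and 2.37), SPRRNA.49 (2.41 and 2.60), SPRRNA.46 (1.88 and 1.996) and SPRRNA.44 (1.75 and 1.964), with many saturated probes in both genotypes. Each of the 3 centromeres held 1 of the 10, nearest to SPATRNAILE.03 (chromosome I, 3765160 to 3776872; 2.78 in wild type and 1.82 in sap1-1), SPBTRNAVAL.07 (chromosome II, 1618549 to 1629742; 2.87 and 1.83) and SPCTRNALEU.12 (chromosome III, 1092977 to 1101796; 2.95 and 1.958). The region upstream of SPAC750.06C stood at 1.37 and 1.94, levels that are inexact because 7 of its 9 probes were saturated in wild type and 8 in sap1-1. The region at pan5 (chromosome II, 4477205 to 4480266) lay in DNA that was missing from the wild-type extract, so its value of 1.31 in wild type does not measure binding.

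Genes of tRNA and protein synthesis had a lower Bqt3 signal in sap1-1. On arms the wild-type Bqt3 array correlated at 0.32 with Bqt3 sap1-1. With Sap1 sap1-1, Taz1 and wild-type Sap1 it correlated at 0.35, 0.34 and 0.33. The signal at these genes therefore need not be Bqt3 binding. The median over tRNA genes fell from 0.44 to 0.07 (difference −0.39, below all matched lists), with all probes lower in 120 of 152 and higher in 10; over the 110 tRNA genes on arms the difference was −0.26 (below all matched lists, 79 lower and 10 higher), and the others lay at or beside centromeres. Over all tRNA genes quantile normalization gave −0.60. Ribosomal protein genes fell from 0.19 to −0.18 (difference −0.41, below all matched lists; 117 of 141 lower, 7 higher; −0.64 with normexp), with rpl1602 at −1.07. Translation factor genes fell from 0.44 to −0.32 (difference −0.76, below all matched lists; 6 of 7 lower; −1.17 with normexp), with tef102 (−1.15), tef103 (−1.0), tef101 (−0.95) and tif1 (−0.76) changing most. Glycolytic genes fell from 0.38 to −0.31 (difference −0.76, below all matched lists; 6 of 9 lower), with pgk1 (−1.06), eno101 (−1.03) and tpi1 (−1.0) changing most. Heat and stress genes fell by 0.44 (percentile 2.25; 7 of 10 lower, 1 higher), with ssa2 at −0.90 and hsp90 at −0.76. The 5S rRNA genes fell by 0.13 (below all matched lists; 18 of 35 lower, 11 higher), which became −0.27 with scaling to one robust SD, −0.37 with quantile normalization and −0.40 with normexp. The 5 largest falls of single genes were the tRNA genes SPCTRNAARG.10 (−1.69), SPBTRNAGLU.06 (−1.60) and SPBTRNAGLY.08 (−1.47), the small nucleolar RNA gene snoU14 (−1.53) and rpb1, the largest subunit of RNA polymerase II (−1.31), and all but snoU14 lay at or beside centromeres, where Bqt3 fell as a class. Tf2 elements had a difference of 0.02 (percentile 1.81, but 3.04 among matched arm lists, within the central 95%). This difference became −0.15 with scaling to one robust SD and −0.22 with quantile normalization. Within the central 95% of matched lists were histone genes (−0.20; hht2, −0.85), MBF targets (0.07; suc22, 0.51), meiotic genes (−0.02; mei4, −1.12; mug9, 0.85), transporters (0.27; str3, 2.04; pma1, −0.81; pho84, 0.80) and LTRs (0.03). Of these, meiotic genes, transporters and LTRs changed sign under at least 1 scaling. Over arm members alone the differences were −0.16 for transporters (6 genes) and −0.03 for LTRs (186). The gene tlh1, at a chromosome end, stood at 0.94 and 1.08, a difference that turned negative with scaling to one robust SD or quantile normalization.

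On the wild-type Bqt3 array 49 subtelomeric probes of chromosome II gave almost no whole-cell extract signal, and without such probes the subtelomeric difference was 1.94. The pair of Bqt3 arrays lay on different slides, the subtelomeric difference was 1.23 in the ChIP channel alone and 1.07 within 20 kb of the ends, and slide and genotype cannot be told apart.

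**Figure D2:**
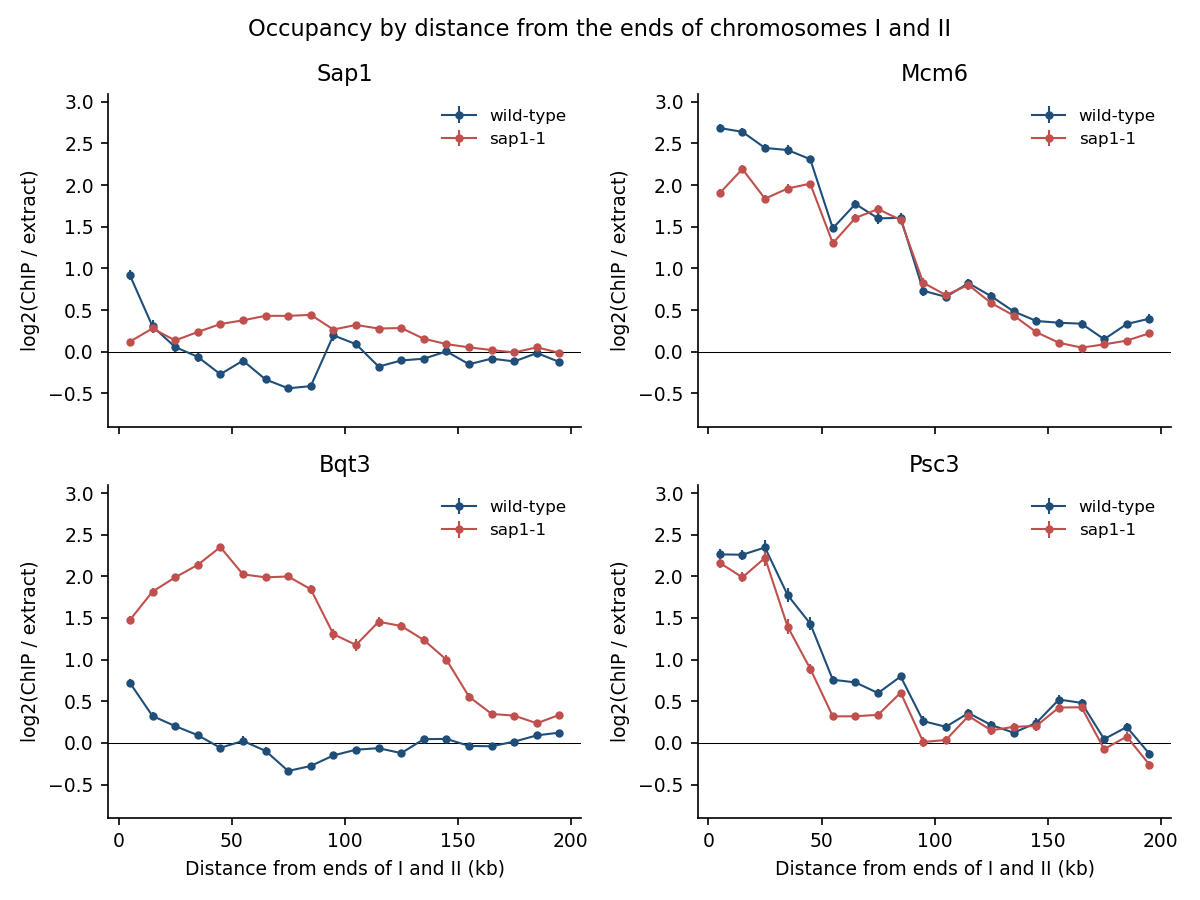
Mean log2 ratio (y axis) in bins of 10 kb from the ends of chromosomes I and II (x axis, to 200 kb) for Sap1, Mcm6, Bqt3 and Psc3, in wild type (blue) and sap1-1 (red), with bars of 1 SE over probes. Bqt3 at 40 to 50 kb is −0.06 in wild type and 2.35 in sap1-1.

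Psc3 in wild type against sap1-1 compares where cohesin sat. Psc3 was enriched at 325 regions in wild type and 389 in sap1-1, and 273 of the 325 overlapped a sap1-1 region by at least 1 bp. Depleted runs numbered 224 and 246, so the Psc3 signal spread widely in both directions and the number of enriched regions alone does not set them apart from the spread. At the 361 averaged regions the median was 1.18 in wild type and 1.40 in sap1-1, a difference of 0.20 (95% interval 0.17 to 0.22), with 291 higher. Arm regions (308) had a median difference of 0.22, with 267 higher, and subtelomeric regions (26) had −0.27, with 22 lower. Over the subtelomeres as a whole the mean fell from 1.17 to 0.86 (difference −0.32, SE 0.05, percentile 0.06; −0.15 with centring on the mode), and centromeres stood at 1.64 and 1.58. These sizes are inexact, since 344 in wild type and 266 in sap1-1 of the 1149 subtelomeric probes and 206 and 186 of the 361 centromeric ones were saturated in the ChIP channel; unsaturated probes gave −0.36 in subtelomeres and −0.43 (155 probes) at centromeres.

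The 10 strongest averaged regions lay at 6 centromeric positions, at 3 subtelomeric ones and at the mating-type region. The first was centromeric DNA nearest to emc5 (chromosome I, 3785583 to 3795546; 2.16 in wild type and 1.89 in sap1-1). The second was subtelomeric, nearest to the pyruvate decarboxylase gene pdc102 (chromosome I, 5527368 to 5569519; 2.59 and 2.19), and the fourth lay beside mat3-Mi in the silent mating-type region (chromosome II, 2127793 to 2137422; 2.20 and 2.20). Others were nearest to SPCTRNAASP.06 (chromosome III, 1085027 to 1089263, at 2.48 and 2.64, and 1090010 to 1095708, at 1.87 and 1.82), SPAC750.07C (2.60 and 2.54), SPCTRNAASP.07 (2.55 and 2.63), SPATRNAALA.05 (2.09 and 2.21), SPAC212.09C (2.55 and 2.32) and SPATRNAPHE.02 (2.44 and 2.57). Many of their probes were saturated in both genotypes, such as 81 in wild type and 59 in sap1-1 of 133 at pdc102, and 17 and 16 of 17 at SPAC750.07C, so the levels are inexact and the order is uncertain.

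Between convergent genes, where cohesin is known to gather, Psc3 was highest in both genotypes. In wild type the mean was 0.23 over 281 convergent regions, −0.18 over 1643 tandem regions and −0.47 over 1063 divergent regions. Convergent exceeded divergent regions by 0.69 (SE 0.04 over regions) in wild type and by 0.79 (SE 0.05) in sap1-1, each above all 10000 reassignments of region type. In sap1-1 the means were 0.33, −0.14 and −0.46.

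**Figure D3:**
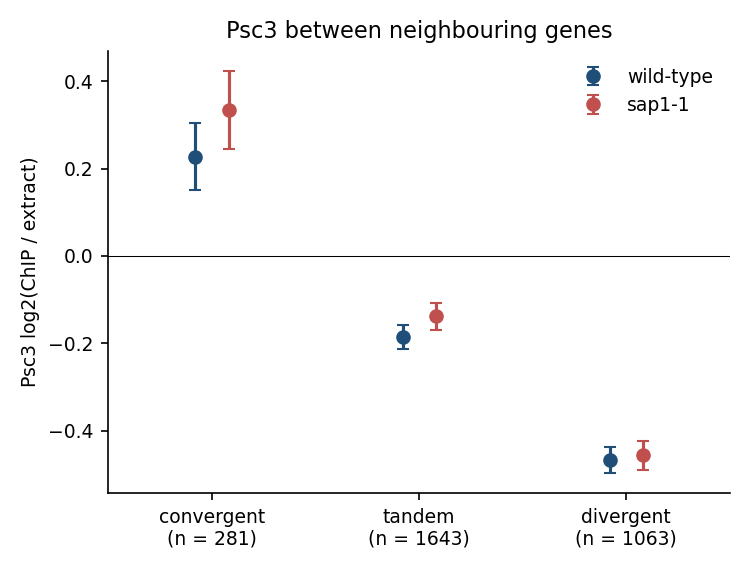
Mean Psc3 log2 ratio (y axis) in convergent, tandem and divergent intergenic regions of chromosome arms, in wild type and sap1-1, with bars of 95% confidence over regions. Convergent regions stand at 0.23 in wild type and 0.33 in sap1-1, and divergent regions at −0.47 and −0.46.

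Among single genes the largest Psc3 fall was at the nucleotide-synthesis gene ura4, a common selection marker (chromosome III, 115589 to 116625), from 2.27 to −0.30, with 5 of its 6 probes saturated in wild type. The next falls were SPAC186.02C (−1.17, with 4 of 8 probes saturated in wild type and 1 in sap1-1), yox1, a repressor of MBF targets that borders centromere II (−1.04), hry1 (−0.88) and SPAC869.04 (−0.85). The largest rises were at the diphthamide synthesis gene dph5 (1.12), the glutaredoxin gene grx3 (0.86), taf7, of the general transcription factor TFIID (0.82), the glyoxalase gene glo1 (0.80) and apc10, of the anaphase-promoting complex (0.79). Probes saturated in sap1-1 (1 of 8 at taf7, 1 of 8 at glo1 and 2 of 6 at apc10) make the last of these sizes and their order inexact. All probes rose in 1223 genes and fell in 788.

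Heat and stress genes had a higher Psc3 signal in sap1-1, with a median difference of 0.32 over 10 genes (above all matched lists). This difference was 0.18 with loess and 0.49 with centring on the mode. All probes were higher in 6 genes and lower in 1, and sti1 (0.72), hsp90 (0.42), hsp9 (0.36) and hsp16 (0.35) changed most. Glycolytic genes fell by 0.18 (percentile 0.63; pdc101, −0.40), and the difference was −0.00 with centring on the mode and −0.30 with loess. Histone genes had −0.12 (percentile 1.91, with hhf1 at −0.37). MBF targets had −0.07 (percentile 2.39, with yox1 at −1.04 and tos4 at 0.36). Over the 11 MBF targets on arms it was −0.06 (percentile 3.76, within the central 95%). The differences of histone genes and MBF targets became 0.05 and 0.11 with centring on the mode. The same choice turned tRNA genes (−0.09, below all matched lists; 64 lower, 30 higher) and LTRs (−0.09, below all matched lists; 72 lower, 34 higher) to 0.09 each. That choice moved the median difference over all genes by 0.17, to 0.20, and the medians of these 5 lists stayed below it. The other lists lay within the central 95% of matched lists, at 0.01 for ribosomal protein genes, 0.02 for 5S rRNA genes, 0.02 for Tf2 elements, −0.08 for translation factor genes, −0.06 for transporters and −0.03 for meiotic genes (the last 3 positive with centring on the mode), and tlh1 stood at 2.25 and 2.45. Both Psc3 arrays lay on one slide, and the ranges of 0.06 (quantile normalization) to 0.36 (centring on the mode) bound the difference at enriched regions over the scalings tried.

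**Figure D4:**
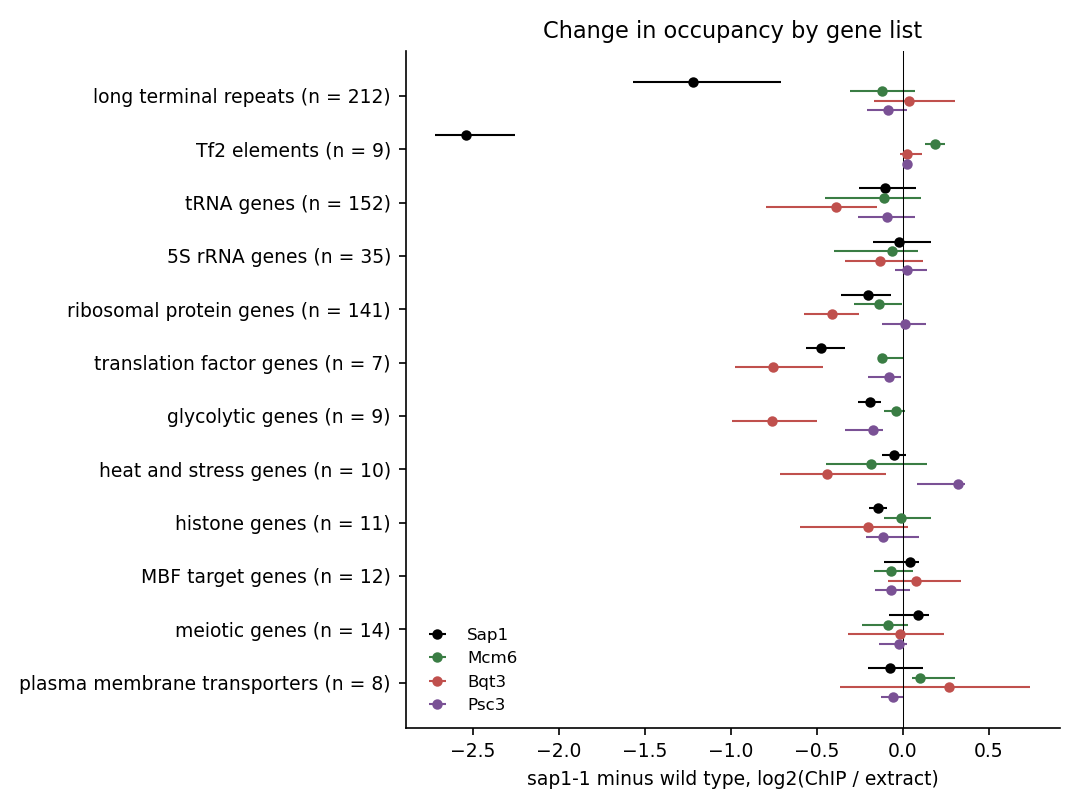
Median difference (sap1-1 minus wild type, log2 ratio, x axis) of 12 gene groups for Sap1, Mcm6, Bqt3 and Psc3, with bars from the lower to the upper quartile over genes. Tf2 elements (−2.54, with probes saturated in both channels in sap1-1) and LTRs (−1.22) stand lowest for Sap1, and translation factor and glycolytic genes (−0.76 each) lowest for Bqt3. The tRNA genes change sign for Sap1 under 2 scalings and for Psc3 with centring on the mode, which moves the median over all genes by 0.17.

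Taz1 in wild type shows where this telomere protein bound away from telomeres. At 2-fold, 51 regions were enriched against 2 depleted runs: 38 on arms, 7 in subtelomeres, 5 at the rDNA ends and 1 at a centromere. The strongest, with the height of the running mean, were within SPAC212.06C (chromosome I, 17006 to 21373; 3.95), upstream of SPBC3H7.08C (chromosome II, 1864018 to 1870130; 3.8), upstream of SPAC750.06C (chromosome I, 5570061 to 5579096; 3.78) and upstream of rcr1 (chromosome II, 2827548 to 2831982; 3.50). They continued with ivn1 (chromosome II, 1494633 to 1502395; 3.35), SPRRNA.47 (3.29), iec1, of the Ino80 chromatin remodeller (chromosome I, 4650198 to 4655357; 3.26), gap1, a Ras GTPase-activating protein gene (chromosome II, 946822 to 950849; 3.23), SPAC806.06C (chromosome I, 243006 to 247180; 3.09) and SPRRNA.49 (3.06). Subtelomeres averaged 0.34 (SE 0.13), with 1.67 in the first 10 kb and 0.02 from 50 to 100 kb.

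The Taz1 regions on arms were compared with Mcm6 to ask whether they lie at replication origins. Over the 38 arm regions Mcm6 averaged 0.74 over both genotypes (SE 0.10, above all 10000 shifts), with 0.76 in wild type and 0.72 in sap1-1. Of the 38, 18 overlapped an averaged Mcm6 region, against a median of 3 among shifts. The Mcm6 average was 0.38 at a 1.5-fold and 1.04 at a 3-fold threshold for Taz1 regions. In gene groups, Taz1 levels relative to random lists were high at Tf2 elements (0.49), tRNA genes (0.37) and 5S rRNA genes (0.36), each above all 10000 lists, and at transporters (0.26, percentile 99.58) and ribosomal protein genes (0.08, percentile 99.98), and low at heat and stress genes (−0.28, below all lists). Levels at Tf2 elements, tRNA genes and 5S rRNA genes also stood at percentile 99.96 or higher for Sap1, Mcm6 and Bqt3, though not for Psc3. High signal there is thus not particular to Taz1. Histone genes (0.13), MBF targets (−0.05), meiotic genes (−0.04), glycolytic genes (−0.06), translation factor genes (0.00) and LTRs (−0.00) were within the central 95% of random lists, and tlh1 stood at 2.21.

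The whole-cell extract channel compares genomic DNA of the genotypes, and its subtelomeric signal shows whether copy number there differed. Relative to each probe's mean over the 9 arrays, subtelomeres averaged 0.02 (SD 0.26, n = 5) in wild type and −0.03 (SD 0.14, n = 4) in sap1-1, a difference of −0.05 with an exact two-sided permutation p of 0.778. Within the 4 proteins measured in both genotypes the difference averaged −0.01. Without the probes missing from a strain, most of them on the wild-type Bqt3 array, these values were −0.15 (exact permutation p = 0.46) and −0.13, and the Bqt3 pair went from −0.24 to −0.69. The difference was 0.27 on the slide that held both Mcm6 arrays, 0.17 on the slide that held 1 wild-type and 2 sap1-1 arrays, and 0.01 on the scanner that read 2 wild-type and 3 sap1-1 arrays. Each other slide held arrays of 1 genotype. Exact permutation p-values of the other classes were 0.587 for centromeres (difference −0.14), 0.349 for the rDNA ends (−0.44) and 0.0952 for probes of cloned telomere-adjacent DNA (0.28), none below 0.05 before any adjustment for the 5 classes tested, mitochondrial probes included (−0.39, p = 0.667).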

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

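The tests of the Bqt3 rise, of the Sap1 fall and of ura4 probes present in both strains were chosen only after the results were seen; the other tests at ura4 were set out before. Mitochondrial probes in the whole-cell extract channel stood out on the Mcm6 sap1-1 array, at 1.01 above each probe's mean over all arrays, against −0.633 to −0.617 on the other 3 sap1-1 arrays, a gap of 0.991 of the group's range; chance sets apart about 1 in 20 such groups. The values divide by scanner: the 5 arrays of scanner 1 lay at −0.688 to −0.593, and the 4 arrays of the other scanners at 0.549 to 1.01, with wild-type Mcm6 on the same slide at 0.713.

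The Bqt3 rise in subtelomeres was 1.91 (SE 0.13). A weaker whole-cell extract signal in sap1-1 (difference −0.69 without the probes missing from the wild-type extract, and −0.24 with them, as they lower the wild-type mean) cannot make up most of it, because the ChIP channel alone rose by 1.23 (SE 0.11), more than the 0.95 that would be 50% of the log ratio difference, and removal of the trend with probe GC content left 1.89 (SE 0.13). A Mcm6 precipitate in place of Bqt3 in sap1-1 was tested first at centromeres, where both arrays differed by 0.42 (SE 0.29), within 2 SE. The second test used 366 arm regions enriched for Mcm6 in wild type. There the Bqt3 sap1-1 array lay below the Mcm6 sap1-1 array by more than 2 SE, at −0.54 (SE 0.03). That SE holds no variation between arrays. At the same 366 regions the Mcm6 arrays themselves differed by a median of −0.86, which the choice of regions on the wild-type array favours. The second test therefore cannot decide on a complete exchange. Weaker precipitation alone would lower all regions, yet in subtelomeres the Bqt3 sap1-1 array (1.90) lay above the Mcm6 one (1.65). An exchange and a partial mixture both stay open, and other values go with a mixture. Over all probes the Bqt3 sap1-1 array correlated at 0.528 with Mcm6 sap1-1 and at 0.317 with Bqt3 wild type. On arms these were 0.314 and 0.322, against 0.696 between the Mcm6 arrays. At the 204 averaged Mcm6 arm regions Bqt3 rose by a mean of 0.43 and a median of 0.28, with 157 higher. Arms of chromosomes I and II begin 100 kb from the ends, and the Bqt3 rise continued there. From 110 to 120 kb Bqt3 stood at −0.06 in wild type and 1.45 in sap1-1, and Mcm6 sap1-1 at 0.80. Part of the rise at these regions may thus be the subtelomeric one. The Bqt3 arrays lay on different slides, so slide and genotype cannot be told apart. A genotype effect on the position of subtelomeres at the nuclear membrane therefore stays open and may account for the rise, as an untested hypothesis.

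The Sap1 fall at its 46 enriched regions was −2.14. A narrower range of the sap1-1 array would have left a fall smaller than 0.93, or 50% of the scaled wild-type median, after scaling to one robust SD, but the fall at the same regions was then −1.63 (95% interval −1.78 to −1.48). A test added later, with quantile normalization, left −1.11 (95% interval −1.30 to −1.02) at the same regions, again a larger fall than 50% of the wild-type median (0.74). Over the 15 regions enriched after that normalization the median was −0.46 (95% interval −0.58 to 1.15), where no fall is called. These 15 regions were defined anew on the normalized arrays. The 46 regions were chosen before scaling, which favours a fall, so the tests at them do not exclude a narrower range. Saturated spots were excluded as the whole cause by the 17 regions without them, at −1.76 (95% interval −1.96 to −1.61). With 0 slides holding Sap1 arrays of both genotypes, slide, scanner and software cannot be told apart from genotype, and a name in the wild-type deposit points to a tagged strain where the label gives a Sap1 antibody, which leaves a difference in precipitation open. Loss of Sap1 binding in the mutant may account for the fall and stays open beside them.

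The Psc3 fall at ura4, a gene often used as a marker at inserted sites, was −2.57 over 6 probes. Of these 5 were saturated in the ChIP channel in wild type and 0 in sap1-1, so the sizes below that involve wild-type Psc3 are lower bounds, and their SE does not cover this. The whole-cell extract at ura4 was lower in sap1-1 by a mean difference of −1.21 (SE 1.31), which rests on 1 missing probe and leaves a deletion of the whole gene undecided by itself. At the 5 probes present in both extracts the Psc3 difference was still −2.59 (SE 0.25) with a whole-cell extract difference of 0.08 (SE 0.31), which argues against missing DNA as the cause there. A candidate explanation, set out before its test, is a copy of ura4 at a cohesin-rich site of the wild-type strain: ura4 exceeded its neighbours 1 to 5 kb away by 2.91 (SE 0.24) in wild type, and those 26 neighbouring probes differed between genotypes by −0.02. The labels do not give the marker genes of the strains, and no biological explanation was tested.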

How the results depend on the processing

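No paired analysis was possible because each group held 1 array, except that the whole-cell extract arrays could be paired by protein; that pairing, added after seeing the data, gave a mean difference of −0.014 over 4 pairs, with an exact sign-flip p of 1 where the smallest possible is 0.125. The ChIP channel alone, the removal of regions with saturated probes, intergenic regions bounded by coding sequences and the removal of probes missing from a strain were chosen after seeing the data. Over all alternatives, 79 of the values that answer a comparison stayed within their interval or within 1.5 times the count, 6 changed sign from a main interval that excluded 0, in 4 of them to an interval that also excluded 0, and 43 others moved, of which the whole-cell extract difference within 1 slide crossed 0; of the values for single genes, lists and classes 439 stayed, 152 moved and 4 changed sign from a main interval that excluded 0, with 0 inside the new interval for Sap1 at tRNA genes under scaling to one robust SD. The cause was not tested for the changes below, except where fewer or other regions enter by construction. The median Sap1 difference at enriched regions (−2.14) became −1.483 with scaling to one robust SD, −0.46 (95% interval −0.58 to 1.15, over 15 regions) with quantile normalization, where the fall is no longer called, −1.85 with loess, −1.73 with unsaturated probes well above background, −1.91 with probes of 1 match, −1.42 at 1.5-fold, −1.49 at 3 robust SDs, −1.43 on wild-type regions and −1.76 without regions holding a saturated probe. It changed sign to 1.70 at the 2 regions defined on sap1-1, and 3-fold left no Sap1 region. The Mcm6 difference at enriched regions (−0.56) became −0.67 with mode centring, 0.29 with scaling to one robust SD, −0.094 with quantile normalization, −0.65 with loess, −0.67 at 1.5-fold, −0.24 at 3-fold, −0.81 on wild-type regions and −0.25 on sap1-1 regions. The Psc3 difference at enriched regions (0.20) became 0.36 with mode centring, 0.092 with scaling to one robust SD, 0.056 with quantile normalization, 0.23 with unsaturated probes, 0.14 at 1.5-fold, 0.12 on wild-type regions and 0.26 on sap1-1 regions. The Mcm6 difference in subtelomeres (−0.22) changed sign with normexp (0.15), scaling to one robust SD (0.79), quantile normalization (0.16) and the ChIP channel alone (0.078), with intervals that include 0 for normexp and for the ChIP channel, and was −0.49 within 50 kb and −0.63 within 20 kb. The Bqt3 difference in subtelomeres (1.91) became 2.82 with normexp, 1.58 with scaling to one robust SD, 1.44 with quantile normalization, 1.07 within 20 kb and 1.23 in the ChIP channel alone. The Psc3 excess at convergent regions became 0.85 with normexp and 0.56 with loess in wild type (0.69), and 0.97 and 0.63 in sap1-1 (0.79). Taz1 regions (51) numbered 106 with normexp, 177 at 1.5-fold, 25 at 3-fold and 88 at 3 robust SDs. Mcm6 at arm Taz1 regions (0.74) was 0.54 with normexp, 0.38 at 1.5-fold, 1.04 at 3-fold and 0.54 at 3 robust SDs. The median differences of tRNA genes changed sign for Sap1 with scaling to one robust SD (0.033) and quantile normalization (0.15), and with mode centring those of tRNA genes (0.086) and LTRs (0.092) changed sign for Psc3. For Psc3 mode centring moved the median difference over all genes by 0.17. Of the named genes, quantile normalization moved the Sap1 rises at SPAC869.04 (1.25) to 1.87, hry1 (1.15) to 1.94 and pfl7 (1.12) to 1.79, and scaling to one robust SD moved the Mcm6 changes at alr2 (0.86) to 1.66, ecl3 (0.71) to 1.24, SPAC186.04C (−1.30) to −0.14 and tim13 (−1.30) to −0.86. Normexp moved the Bqt3 falls at SPCTRNAARG.10 (−1.69) to −1.103, SPBTRNAGLU.06 (−1.60) to −2.63, SPBTRNAGLY.08 (−1.47) to −2.52 and rpb1 (−1.31) to −2.18. The whole-cell extract difference in subtelomeres was −0.15 without probes missing from a strain, 0.27 within the slide of the Mcm6 arrays, and ranged from −0.14 to 0.03 without each array in turn. The deposited table was not used for Mcm6, whose score is not a log ratio. Signals lay well above background at 99.9% to all of the probes on each array, and saturation, with up to 2326 ChIP probes per array, limits high values.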

Other observations

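The test of the shorter repeat unit was set out before its result; the values before it were selected after the data were seen. Probes of cloned telomere-adjacent DNA, which were not placed on the chromosomes here, held the highest Taz1 signal of the classes measured, at 3.63 (SE 0.18 over 126 probes). Sap1 at the same probes went from 2.36 in wild type to 0.31 in sap1-1, a difference of −2.02 (SE 0.14, 114 probes), with 67 of 129 probes saturated in sap1-1 and 4 in wild type. Mcm6 stood at 1.44 and 1.46 there, Psc3 at 1.39 and 1.41, and Bqt3 at 1.82 and 1.55, where many Psc3 and Bqt3 probes were saturated (91 and 84, and 97 and 85). In the mating-type region (chromosome II, 2109219 to 2138394) Sap1 went from 0.65 to 0.11 (difference −0.53, SE 0.09, percentile 0.63 among shifts; 23 of 154 probes saturated in sap1-1 and 0 in wild type), and Bqt3 from 0.46 to 0.60.

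The proteins shared sites unequally. At the 204 Mcm6-enriched arm regions Taz1 averaged 0.37, above all 10000 shifts, and Psc3 averaged −0.34 in wild type, below all of them. Bqt3 at those regions stood at 0.01 in wild type and 0.44 in sap1-1, a difference of 0.43 (SE 0.09, above all shifts), with 157 of 204 regions higher. The median over regions was 0.28, and part of this rise may be the subtelomeric one, which extended into the arms. At the 197 arm regions where Sap1 was enriched in wild type the differences of the other proteins were −0.04 for Mcm6 (SE 0.02, percentile 53.54), −0.10 for Bqt3 (SE 0.02, percentile 2.67) and −0.05 for Psc3 (SE 0.01, percentile 0.48).

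Runs of at least 3 consecutive probes were missing or low in 3 of the 9 whole-cell extracts. The Bqt3 wild-type extract lacked 39 probes on chromosome II from 4475146 to 4487917, which hold SPBPB2B2.08, pan5, gal7, tgd1 and gal10 (median −9.50 relative to the other arrays), and 10 probes from 4488716 to 4492126 at gal1 (−9.48). The Bqt3 sap1-1 extract lacked 5 probes at ura4 (chromosome III, 115679 to 116940; −9.83). The Psc3 sap1-1 extract was low at 3 probes from 1083986 to 1085957 on chromosome III (−3.25), within centromere III.

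Taz1 binds telomere repeats that contain GGTTACA. The genome holds 14 neighbouring pairs of it within 100 bp, and 0 of the 38 arm Taz1 regions had such a pair. These regions thus lay away from such pairs, but a count of 0 is also the median among shifts. At least 1 copy lay within 500 bp of 7 regions, against a median of 8 among shifts. Taz1 averaged 0.03 (SD 0.30) at 988 single copies on arms and 0.20 (SD 0.22) at 7 sites with 2. A shorter repeat unit, GGTTAC, might have marked these regions, but 2 of the 38 had 2 copies of it within 100 bp, against a median of 1 among shifts and 3 at the upper bound of their central 95%, which argues against the shorter unit as a mark of most of these regions.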
